A study of Rattus norvegicus with 8 samples.

How the data were processed

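Total RNA from 8 cultures of rat ventricular cardiomyocytes was labelled with biotin by a whole-transcript sense-strand protocol and hybridised to 1 Affymetrix array per culture, per the labels' protocols, after extraction on silica columns. The deposited table holds 1 linear intensity per probe set and array (29214 probe sets, 8 arrays), as the size and range of its values show, and every column was matched to a culture by its labels. How the authors summarised probes into these intensities, corrected background or normalized arrays is not given in the sources used here. A summary of probes that shares a scale over arrays can shrink differences of dim genes, and this was not tested. Of all values, 198 lay under an intensity of 1. No column belonged to a sample outside the study. Cultures were assigned to the LacZ group (4 arrays) or the YAP1 group (4 arrays) by their labels.

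Probe sets were named through the platform's annotation, which is older than current gene names. Of 29214 probe sets, 15310 carried 1 gene symbol, 323 several and 13581 none, and those with several or none were left unnamed. Symbols were updated by gene identifier through the NCBI RefSeq gene table of assembly GRCr8 for 15279 probe sets, and the annotated symbol was kept for 31. That table was used for names alone, since the annotation names no build, and no coordinates are given. Where a gene had more than 1 probe set (527 genes), the one with the highest mean over all 8 arrays stood for it, which left 14506 genes.

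The fixed design assumed log2 values, with a move to log2 if the table proved linear, and so log2(intensity + 1) was taken with a pseudocount of 1. A fold change on this scale understates the change of dim genes. Arrays were left as deposited, because their medians differed by at most 0.112 and their upper quartiles by at most 0.0823 on the log2 scale, while the lower quartiles differed by up to 0.293. No filter on dim genes was applied. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 4.85 prior degrees of freedom), with Benjamini-Hochberg adjustment over 14506 genes and a threshold of 0.05. The median standard error of a log2 fold change was 0.1003. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

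Before the data were examined, 27 gene lists were fixed from textbook knowledge, with 539 entries of which 477 were measured, and some genes stand in more than 1 list. Lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 27 lists, and again with the correlation estimated per list. The rule for named genes was fixed at the same time. It takes Yap1, the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap and whose symbol is no placeholder, up to 3 rises and 3 falls per list among genes past the threshold, and 14 genes of prior interest, of which Mki67 was not measured by a probe set with 1 symbol.

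Alternatives fixed before the data were examined were quantile normalization, centring on array medians, leaving out the dimmest 25% or 50% of genes, averaging a gene's probe sets, testing all probe sets, trended robust eBayes, array weights, the replicate number as a block, a test against a 1.2-fold change, and each array left out in turn. For lists, fry and an exact permutation test of the list mean per array were added, for which the smallest p of 4 arrays against 4 is 0.02857. A pseudocount of 16, and leaving out LacZ replicate 2 together with YAP1 replicate 4, were chosen after seeing the data.

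The procedure was tested on simulated data for the YAP1 against LacZ comparison with 14506 genes. It recovered 4% of genes changed by 0.25 on the log2 scale, 58% of those changed by 0.5, 96% of those changed by 1 and 100% of those changed by 2. Beside 200 changed genes it called 11 unchanged ones, and it called 0 with no change simulated. In the data 3591 genes were called, and the adjustment is stricter where fewer genes change. The recovered shares therefore hold for the simulated setting and can understate those in the data. A planted gene list was called, and 0 of 20 unchanged lists were. Each gene was simulated on its own, so this does not test lists whose members move together. In the data the estimated correlation was 0.64 for the interferon list and 0.35 for the mitosis list. No 2 arrays held the same values, and the closest pair within a group differed by a median of 0.0676 on the log2 scale.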

Results

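Gene expression was measured on Affymetrix arrays in ventricular cardiomyocytes isolated from rats at postnatal day 4. The cells had been kept for 48 h with cytosine arabinoside (AraC), a nucleoside that kills dividing cells such as fibroblasts, and then for 48 h without serum in the presence of an adenovirus. Of the 8 cultures, 4 received an adenovirus for LacZ, the bacterial gene for beta-galactosidase that serves as a control, and 4 received an adenovirus for FLAG-tagged YAP1 in its activated form. YAP1 is the transcriptional co-activator that the Hippo kinases restrain, and it binds DNA through the TEAD factors. The design text calls the 4 cultures of a group biological replicates. Median intensity per array lay between 174.1 and 188.2 over 29214 probe sets, and the number of arrays limits the precision. The first principal component held 62.0% of the variance over 14506 genes and separated the groups. On the next component, which held 15.4%, YAP1 replicate 4 lay at -23.2 and the other arrays between -9.68 and 14.9. Pairs of arrays within a group correlated at 0.986 to 0.997 across genes, and pairs from different groups at 0.968 to 0.979.

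The comparison of YAP1 with LacZ cultures asks which genes respond to activated YAP1 in cardiomyocytes, and in particular whether genes of proliferation do. Genes of mitosis rose together with YAP1, with all 32 measured members higher and a median log2 fold change of 1.63. Of 15 cardiac transcription factors 11 rose and 0 fell, and of 22 genes of calcium handling and ion channels 16 rose and 1 fell. Among those that rose were Irx4, a ventricular homeobox factor, by 2.52 ± 0.10 (SE) on the log2 scale and Cacnb2, a subunit of the L-type calcium channel, by 2.32 ± 0.11. Genes of the interferon response fell in 22 of 23 cases with a median log2 fold change of -2.11, led by the antiviral gene Oasl at -3.60 ± 0.15. Of 16 listed targets of YAP and TEAD, 3 rose and 5 fell. In all, 1727 of 14506 genes were higher and 1864 lower in the YAP1 cultures, of which 248 and 158 changed at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). The arrays measured whole cultures, so they do not show which cells carried a change, that of the mitosis genes included. Each group received its own virus, so for every gene a difference between the viruses cannot be told apart from an effect of YAP1.

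Intensities are means ± SD over the 4 arrays of a group, fold changes are YAP1 minus LacZ on the scale of log2(intensity + 1) with their standard error, and adjusted p-values are limma's over all genes unless a list is named. The probe set for rat Yap1 (10914811) read 791 ± 46.1 in LacZ and 937 ± 26.2 in YAP1 cultures, a log2 fold change of 0.25 ± 0.07 (adjusted p = 0.0331). How far this probe set matches the transgene was not given in the sources used here, so the value does not check the labels. The Yap1 call was lost when LacZ replicate 2, 3 or 4 or YAP1 replicate 1, 2 or 3 was left out, with adjusted p-values of 0.0638, 0.0683, 0.0514, 0.1005, 0.105 and 0.0506.

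**Figure D1:**
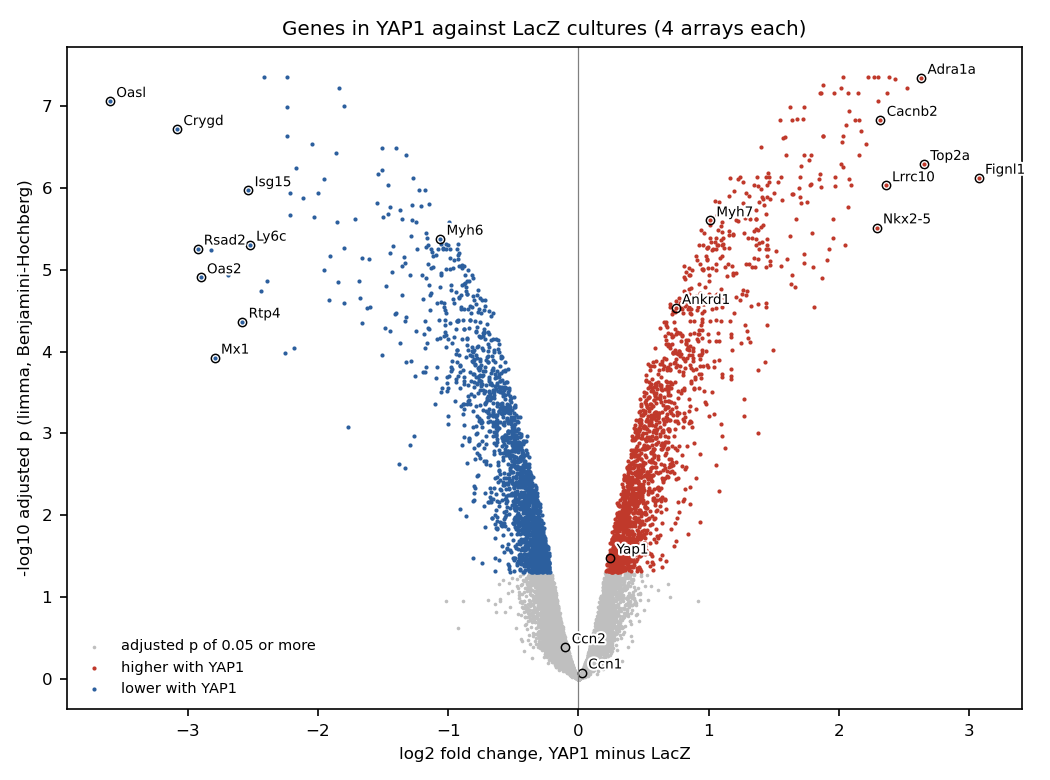
Each point is 1 of 14506 genes, with the log2 fold change of YAP1 over LacZ cultures (4 arrays each) on the horizontal axis and -log10 of limma's adjusted p on the vertical axis, and circled genes are labelled. The 1727 red genes were higher and the 1864 blue genes lower with YAP1, and Ccn1 and Ccn2 lie near the bottom centre.

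The 12 largest rises among genes whose groups did not overlap began with Fignl1, an ATPase of homologous recombination, which went from 50.1 ± 11.5 to 427 ± 79.7 (log2 fold change 3.07 ± 0.18, adjusted p = 7.58e-07). Top2a, the topoisomerase of dividing cells, rose from 298 ± 55.5 to 1865 ± 259 (2.65 ± 0.15, adjusted p = 5.14e-07). Adra1a, the alpha-1A adrenergic receptor, rose from 163 ± 10.1 to 1020 ± 114 (2.63 ± 0.10). Ripor2, the muscle RNA-binding protein gene Rbm24, the T-type calcium channel gene Cacna1g, the cardiac leucine-rich repeat gene Lrrc10 and the small heat shock gene Hspb3 rose by 2.30 to 2.43. Irx4, Cacnb2, Ccnb1 and Nkx2-5 complete the 12. Among the 12 largest falls, Oasl, Rsad2, Bst2, Mx1, Herc6, Ifit3, Mx2 and Isg15 belong to the interferon list, and Oas2 and Rtp4 are also known to be induced by interferon. The lens crystallin gene Crygd went from 196 ± 30.6 to 22.4 ± 4.22 (-3.08 ± 0.15), and the surface antigen gene Ly6c fell by 2.52 ± 0.20. The LacZ value of Fignl1 lies close to, and the YAP1 value of Crygd below, the median LacZ intensity of 215 chemosensory receptor genes (49.0), and Oas2 read below it in YAP1 replicates 3 and 4 (44.6 and 28.8) and Rsad2 and Rtp4 in YAP1 replicate 4 (32.0 and 46.3). These values are not shown to exceed background, so the sizes and ranks of these 5 changes are uncertain. The level used here is a median, so values not far above it are not shown to exceed background either. In YAP1 replicate 4 this holds for Mx1, Ifit3, Ly6c, Bst2 and Herc6, and the sizes and ranks of their falls are uncertain too. Groups did not overlap for 4021 genes, or 27.7% of those tested, where chance gives 2.86%.

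**Figure D2:**
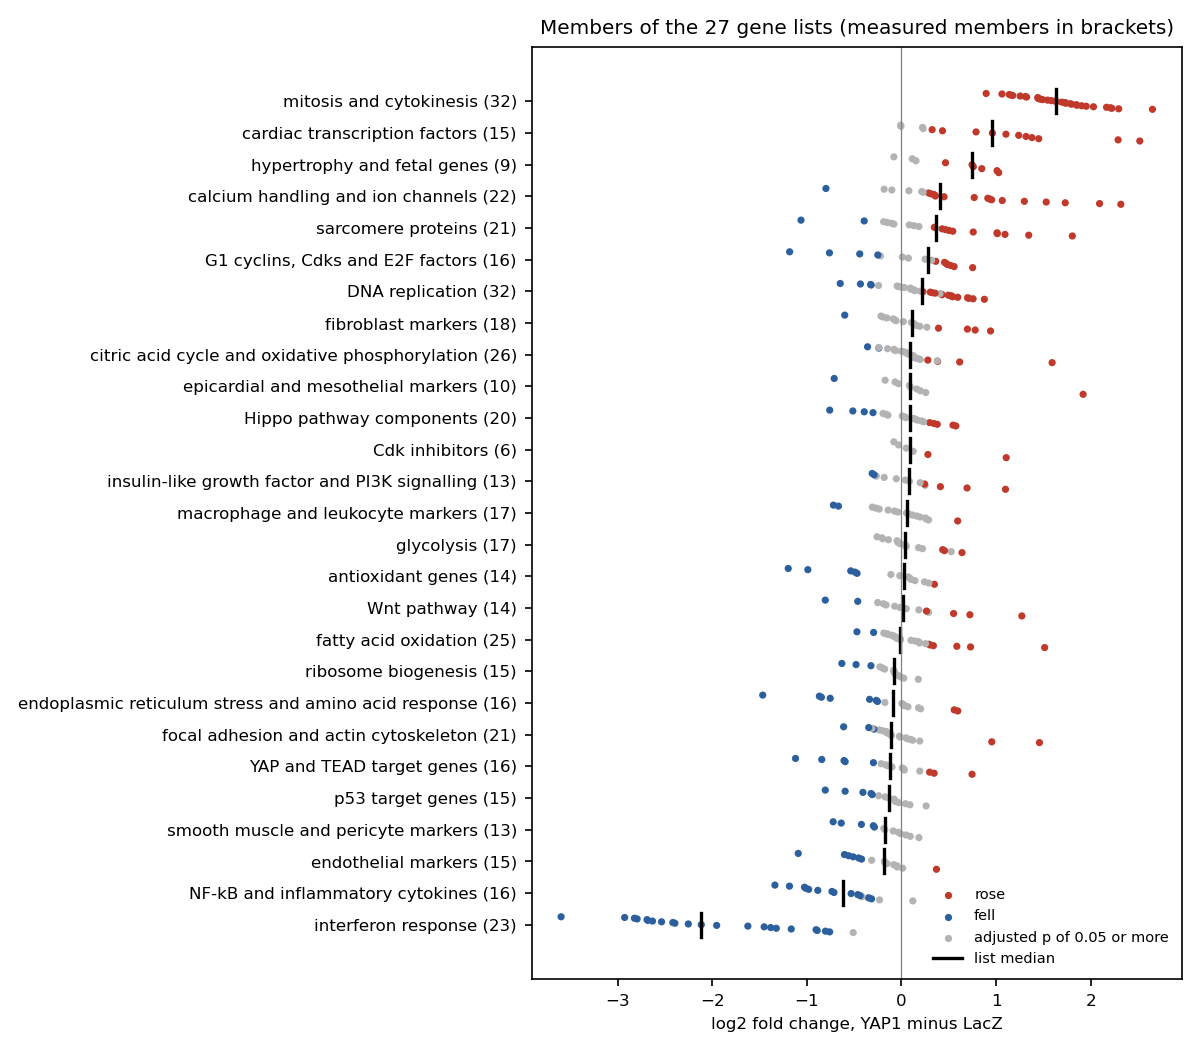
Each row is 1 of 27 gene lists and each point a measured member, with the log2 fold change of YAP1 over LacZ cultures on the horizontal axis, red for members that rose, blue for members that fell, grey for those that did not pass the test, and a black bar at the list's median. The mitosis list lies wholly to the right (median 1.63) and the interferon list wholly to the left (median -2.11).

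Among genes of the cell cycle, the mitosis and cytokinesis list rose in 32 of 32 measured members, and in 32 adjusted over the list alone (camera, adjusted p over the lists = 1.58e-39, and adjusted p = 0.0373 with an estimated correlation). Ccnb1, the cyclin that drives entry into mitosis, rose from 231 ± 11.2 to 1140 ± 94.9 (2.30 ± 0.08). Its kinase Cdk1 rose from 230 ± 11.3 to 834 ± 46.2 (1.86 ± 0.08), the microtubule depolymerase Kif2c by 2.22 ± 0.08 and the chromosome passenger kinase Aurkb by 1.44 ± 0.12. Of 32 measured DNA replication genes, 15 rose and 4 fell, or 16 and 4 adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.000392). The replication call was lost with the correlation estimated from the data (adjusted p = 0.408 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.88 ± 0.11 and the replicative helicase component Cdc45 by 0.71 ± 0.10, whereas the histone mRNA-binding gene Slbp fell by 0.65 ± 0.11 and the helicase subunit Mcm6 by 0.43 ± 0.11.

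The list of G1 cyclins, Cdks and E2F factors had 7 members that rose and 4 that fell of 16, or 9 and 4 adjusted over the list alone. It did not pass camera (adjusted p = 0.146), whereas fry called it higher (fry adjusted p = 0.00342). Ccnd1, the cyclin D gene that couples growth signals to the cycle, rose from 1726 ± 84.4 to 2541 ± 150 (0.56 ± 0.08), Ccnd2 rose by 0.52 ± 0.10 and E2f7, a repressor of E2F targets, by 0.75 ± 0.09. The growth regulator Myc fell by 1.18 ± 0.07, Ccne2 by 0.76 ± 0.08 and Cdk4 by 0.44 ± 0.11. Of 6 Cdk inhibitors 2 rose and none fell, likewise adjusted over the list alone (adjusted p = 0.146). These were Cdkn2c at 1.11 ± 0.08 and Cdkn2b at 0.28 ± 0.08, and the call of Cdkn2b was lost without LacZ replicate 1 (adjusted p = 0.0611) or YAP1 replicate 1 (adjusted p = 0.0742). The Cdk inhibitor list too was called higher by fry (fry adjusted p = 0.00291).

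Among the 16 measured YAP and TEAD targets, 3 rose and 5 fell, or 4 and 5 adjusted over the list alone (median -0.12, camera adjusted p = 0.279). The mean of this list per array, compared with no other genes, differed by -0.15 on the log2 scale (exact permutation p = 0.02857, the smallest possible), and fry gave an adjusted p of 0.00948 for a fall. Ankrd1, which encodes a cardiac ankyrin repeat protein of the nucleus and sarcomere, rose from 5515 ± 272 to 9254 ± 417 (0.75 ± 0.07, adjusted p = 2.95e-05). The coagulation factor receptor F3 rose by 0.35 ± 0.09 and the angiomotin relative Amotl2 by 0.30 ± 0.09. The F3 call was lost without YAP1 replicate 1 or 2 (adjusted p-values 0.0551 and 0.0503), and that of Amotl2 was lost in 5 of the 8 fits that left out 1 array, with adjusted p-values of 0.0607, 0.0783, 0.0626, 0.0955 and 0.121 without LacZ replicates 1, 2 and 3 and YAP1 replicates 1 and 2. Ccn1 read 7185 ± 235 and 7322 ± 285 (0.03 ± 0.07, adjusted p = 0.837) and Ccn2 6470 ± 344 and 6039 ± 326 (-0.10 ± 0.08, adjusted p = 0.411). Fjx1 fell by 1.12 ± 0.09, the ecto-nucleotidase Nt5e by 0.84 ± 0.08 and the receptor kinase Axl by 0.61 ± 0.09. Of 20 Hippo pathway components 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.414). Mob1b, a cofactor of the Lats kinases, rose by 0.58 ± 0.11 and Tead1 by 0.38 ± 0.09, while Tead2 fell by 0.76 ± 0.10 and Rassf1 by 0.39 ± 0.07.

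Among cardiac genes, 11 of 15 transcription factors rose and none fell, or 13 and 0 adjusted over the list alone (median 0.96, camera adjusted p = 6.95e-12, and adjusted p = 0.0208 with an estimated correlation). Nkx2-5, a homeobox factor of cardiac development, rose from 405 ± 97.6 to 1959 ± 329 (2.29 ± 0.17) and the T-box factor Tbx5 by 1.45 ± 0.08. Of 22 genes of calcium handling and ion channels 16 rose and 1 fell, or 18 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 6.40e-10, and adjusted p = 0.0208 with an estimated correlation). Hcn4, the pacemaker channel, rose by 2.09 ± 0.13 and Ryr2, the calcium release channel, by 1.73 ± 0.14, while Kcnd2, a potassium channel of the transient outward current, fell by 0.80 ± 0.08. The sarcomere list held 11 of 21 members that rose and 2 that fell, or 12 and 3 adjusted over the list alone (median 0.36, camera adjusted p = 0.000116, lost at adjusted p = 0.256 with an estimated correlation). Ttn, the giant spring protein titin, rose by 1.81 ± 0.18, Myom1 by 1.35 ± 0.11 and Mybpc3 by 1.09 ± 0.12. In YAP1 replicate 4, Ttn, Ryr2, Myom1 and Mybpc3 read below the other YAP1 arrays, at 11.8, 10.6, 10.3 and 10.8 against medians of 12.5, 11.2, 10.8 and 11.2 on the log2 scale.

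The cardiac myosin heavy chains Myh7 and Myh6 moved in opposite directions, since Myh7, the slow isoform that prevails in the fetal rat ventricle, rose from 3380 ± 73.1 to 6816 ± 330 (1.01 ± 0.07, adjusted p = 2.51e-06) and Myh6, the fast isoform of the adult rat ventricle, fell from 1612 ± 127 to 771 ± 29.7 (-1.06 ± 0.08, adjusted p = 4.21e-06). Tnni3, cardiac troponin I, fell by 0.39 ± 0.08, and Tnnt2, cardiac troponin T, read 6453 ± 377 and 7073 ± 352 (0.13 ± 0.08, adjusted p = 0.263). Of 9 hypertrophy and fetal genes 6 rose and none fell, likewise adjusted over the list alone (median 0.75, camera adjusted p = 1.50e-05, lost at adjusted p = 0.161 with an estimated correlation). Nppb, the gene of B-type natriuretic peptide, rose from 4279 ± 579 to 8688 ± 649 (1.03 ± 0.10). Nppa, the gene of the atrial peptide, read 9424 ± 328 and 10202 ± 193 (0.11 ± 0.07, adjusted p = 0.277), with all 4 YAP1 arrays above all 4 LacZ arrays. It is brighter than Ccn1 and Ccn2, the highest values of the arrays were 12303 to 13295, and a larger rise compressed at this intensity stays open.

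**Figure D3:**
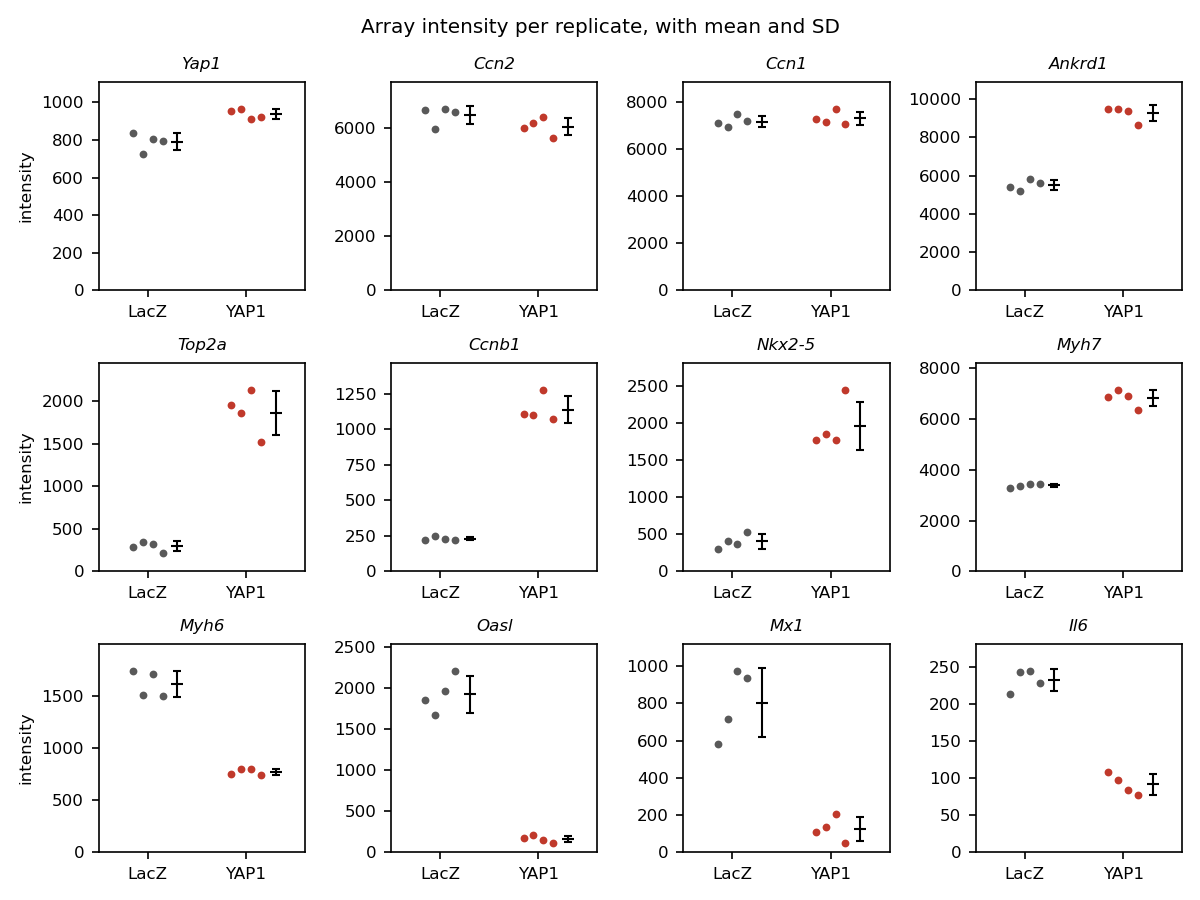
Array intensity on a linear scale (vertical axis) of 12 genes in each LacZ (grey) and YAP1 (red) replicate, with the mean and SD of each group beside the points. Top2a, Ccnb1, Nkx2-5 and Myh7 lie higher in all 4 YAP1 arrays than in all 4 LacZ arrays, Myh6, Oasl, Mx1 and Il6 lie lower in all 4, and the groups overlap for Ccn1 and Ccn2.

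The interferon response list fell in 22 of 23 members and in 23 adjusted over the list alone (median -2.11, camera adjusted p = 4.97e-20). The call of this list was lost with the correlation estimated from the data (adjusted p = 0.161 with an estimated correlation). Compared with no other genes, the list was lower by fry (fry adjusted p = 0.000137). Its mean per array had an exact permutation p of 0.02857, the smallest possible and not adjusted over the lists. Oasl fell from 1927 ± 225 to 161 ± 37.1, the antiviral GTPase Mx1 from 803 ± 185 to 126 ± 62.8 (-2.79 ± 0.34) and the ubiquitin-like modifier Isg15 from 1102 ± 153 to 192 ± 40.4 (-2.53 ± 0.16). The list mean was 9.91 ± 0.12 in LacZ arrays and 7.97 ± 0.37 in YAP1 arrays on the log2 scale, and YAP1 replicate 4 lay at 7.41 against a median of 8.13 in the other YAP1 arrays. Of 16 NF-kB and inflammatory cytokine genes 13 fell and none rose, or 14 and 0 adjusted over the list alone (median -0.62, camera adjusted p = 7.21e-08, lost at adjusted p = 0.15 with an estimated correlation). The cytokine Il6 fell from 232 ± 14.7 to 92.1 ± 14.1 (-1.34 ± 0.11), the apoptosis inhibitor Birc3 by 1.18 ± 0.13 and the chemokine Ccl20 by 1.02 ± 0.11. Markers of macrophages and leukocytes showed no common direction beside these lists, with 1 that rose and 2 that fell of 17, likewise adjusted over the list alone (adjusted p = 0.754). Their median was 0.05 and their mean -0.03, and camera's direction was up. Cd14, the lipopolysaccharide co-receptor, fell by 0.72 ± 0.15 and the lysosomal marker Cd68 by 0.67 ± 0.16, while Csf1r, the receptor of macrophage growth factor, rose by 0.59 ± 0.15 and lost its call with LacZ replicate 2 and YAP1 replicate 4 both left out (adjusted p = 0.0685).

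Markers of other cell types that the cultures could hold moved in different directions beside the cardiac genes. Of 15 endothelial markers 1 rose and 6 fell, likewise adjusted over the list alone (median -0.18, camera adjusted p = 0.00675, lost at adjusted p = 0.391 with an estimated correlation). Flt1, a receptor of vascular growth factor, fell by 1.09 ± 0.09, Esam by 0.60 ± 0.08 and endoglin, Eng, by 0.56 ± 0.08. Tek, which rose by 0.37 ± 0.11, lost its call without LacZ replicate 2 or 4 or YAP1 replicate 1, 2 or 3, with adjusted p-values of 0.0696, 0.087, 0.0946, 0.1004 and 0.0959. Of 13 smooth muscle and pericyte markers 5 fell and none rose, likewise adjusted over the list alone (adjusted p = 0.0913), with the pericyte genes Kcnj8 at -0.72 ± 0.08 and Rgs5 at -0.64 ± 0.14. Of 18 fibroblast markers 4 rose and 1 fell, likewise adjusted over the list alone (adjusted p = 0.146). The matrix genes Dpt, Lum and Fbln2 rose by 0.94 ± 0.11, 0.78 ± 0.09 and 0.70 ± 0.09, and the surface marker Thy1 fell by 0.60 ± 0.12. Of 10 epicardial and mesothelial markers 1 rose and 1 fell, or 3 and 1 adjusted over the list alone (adjusted p = 0.298). These were the keratin Krt18 at 1.92 ± 0.15 and Tbx18 at -0.71 ± 0.10. The 3 probe sets of Krt18 disagreed, since 2 rose by 1.92 and 2.06 and the other read 0.55 ± 0.40. Compared with no other genes, the fibroblast and epicardial lists were higher by fry (fry adjusted p = 0.02 and 0.0226). The smooth muscle and endothelial lists were lower by fry (fry adjusted p = 0.00187 and 0.00291). The exact permutation p of the list mean was 0.0571 for fibroblast markers and 0.02857 for the other lists named here, not adjusted over the lists.

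Genes of energy metabolism changed singly, and their lists did not pass camera. Fry, which compares a list with no other genes, called 2 of them higher. These were fatty acid oxidation (fry adjusted p = 0.0469) and the citric acid cycle and oxidative phosphorylation (fry adjusted p = 0.0468). The list mean of fatty acid oxidation differed by 0.12 (exact permutation p = 0.02857, not adjusted over the lists). Of 25 fatty acid oxidation genes 6 rose and 2 fell, likewise adjusted over the list alone, with a median of -0.01 and a mean of 0.12 and camera's direction up (adjusted p = 0.146). The receptor Ppara, which controls this pathway, rose by 1.51 ± 0.12, the acyl-CoA synthetase Acsl1 by 0.73 ± 0.14 and the muscle carnitine transferase Cpt1b by 0.59 ± 0.08, and the thiolase Acaa2 fell by 0.47 ± 0.08. Of 26 genes of the citric acid cycle and oxidative phosphorylation 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.0811). That list would pass without LacZ replicate 1 (adjusted p = 0.0296), LacZ replicate 4 (adjusted p = 0.0211) or YAP1 replicate 4 (adjusted p = 0.0344). Ppargc1a, the co-activator of mitochondrial biogenesis, rose from 335 ± 30.5 to 1011 ± 56.4 (1.59 ± 0.09). Of 17 glycolysis genes 3 rose and none fell, likewise adjusted over the list alone (adjusted p = 0.298), namely Pfkp at 0.64 ± 0.11, Hk1 at 0.46 ± 0.08 and Pfkfb3 at 0.44 ± 0.10.

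Stress and growth lists did not pass camera either. Fry called the endoplasmic reticulum stress, antioxidant, p53 and ribosome biogenesis lists lower (fry adjusted p = 0.00291, 0.00881, 0.00342 and 0.02). It called the insulin-like growth factor and PI3K list higher (fry adjusted p = 0.0036). The list mean of each had an exact permutation p of 0.02857, not adjusted over the lists. Of 16 genes of endoplasmic reticulum stress and the amino acid response 2 rose and 7 fell, or 3 and 7 adjusted over the list alone (adjusted p = 0.257), with the stress factors Atf3 at -1.47 ± 0.10 and Ddit3 at -0.85 ± 0.11 and the glutathione-degrading Chac1 at -0.87 ± 0.10. Of 14 antioxidant genes 1 rose and 5 fell, or 2 and 5 adjusted over the list alone, with a median of 0.03, a mean of -0.18 and camera's direction down (adjusted p = 0.414). Hmox1, heme oxygenase, fell from 387 ± 45.0 to 169 ± 21.7, and the sulfiredoxin Srxn1 fell by 0.99 ± 0.09 and the mitochondrial superoxide dismutase Sod2 by 0.54 ± 0.10. Of 15 p53 targets 5 fell and none rose, likewise adjusted over the list alone (adjusted p = 0.0811), among them the pro-apoptotic Pmaip1 at -0.80 ± 0.11 and Gadd45a at -0.59 ± 0.08. Of 15 ribosome biogenesis genes 3 fell and none rose, likewise adjusted over the list alone (adjusted p = 0.146), namely Gnl3 at -0.63 ± 0.10, Wdr12 at -0.48 ± 0.11 and Nolc1 at -0.32 ± 0.07. Without LacZ replicate 2 the smooth muscle, p53 and ribosome biogenesis lists would pass as lower (adjusted p-values 0.021, 0.021 and 0.0492).

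Of 13 genes of insulin-like growth factor and PI3K signalling 4 rose and 2 fell, or 6 and 3 adjusted over the list alone (adjusted p = 0.167). The kinase subunit Pik3cb rose from 333 ± 22.4 to 715 ± 63.3 (1.10 ± 0.09) and the insulin receptor Insr by 0.69 ± 0.11, while the growth factor Igf1 fell from 1568 ± 91.1 to 1266 ± 70.8 (-0.31 ± 0.08, adjusted p = 0.0141). Of 14 Wnt pathway genes 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.353). The receptor Fzd1 rose by 1.27 ± 0.09 and the secreted antagonist Sfrp2 by 0.72 ± 0.09, while the Wnt effector Lef1 fell by 0.80 ± 0.10 and the feedback inhibitor Nkd1 by 0.46 ± 0.09. Of 21 focal adhesion and actin genes 2 rose and 3 fell, likewise adjusted over the list alone, with a median of -0.11, a mean of 0.005 and camera's direction down (adjusted p = 0.519). The integrin Itgb5 rose by 1.46 ± 0.12 and the membrane linker Ezr by 0.96 ± 0.08, and the annexin Anxa1 fell by 0.61 ± 0.08. Among the 9 lists that passed with the preset correlation, the mitosis, calcium and cardiac transcription factor lists also passed with an estimated correlation and the other 6 did not. All 9 were called by fry in camera's direction, with a largest fry adjusted p of 0.011 for DNA replication.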

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

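The tests of explanations and the splits of the arrays in this part were chosen after the results they bear on had been seen, whereas the search for arrays that stand apart, the array weights, the test of all probe sets and the permutation test of list means were planned. The search set the gap between an array and its nearest neighbour against the range of its group of 4 at a limit passed by chance in about 1 of 20 cases, over 318 groups of values. It found 22, where chance gives 15.9.

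YAP1 replicate 4 accounts for 12 of these. It lay below the other YAP1 arrays, with gaps of 0.926 of the range for Ttn, 0.911 for Ryr2, 0.892 for Myom1, 0.845 for Mybpc3, 0.893 for Ankrd1, 0.839 for Rsad2, 0.872 for Tek and 0.957 for Wwc2, and above them for Nkx2-5 (0.862). It was also lowest in the means of the interferon list (0.893), the fibroblast list (0.88) and the ribosome biogenesis list (0.909). LacZ replicate 2 lay below the other LacZ arrays for Ccn2 (0.848), Sdha (0.925) and the means of the sarcomere list (0.85) and the glycolysis list (0.887), and above them for Ppargc1a (0.878). LacZ replicate 4 stood apart for Chac1 (0.861, high), Flt1 (0.833, low) and Pik3cb (0.855, low), LacZ replicate 1 for Cdkn2b (0.848, low) and YAP1 replicate 3 for Creld2 (0.91, high). Array weights fitted from the data were lowest for YAP1 replicate 4 (0.293) and LacZ replicate 2 (0.385).

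The comparison by gene left out 13904 probe sets without 1 gene symbol. When all probe sets were tested with limma, 1506 of these changed, 755 higher and 751 lower with YAP1, and 175 and 95 of them at least 2-fold.

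The fall of the interferon list may reflect fewer macrophages in the YAP1 cultures. The 9 macrophage and leukocyte markers brighter than the LacZ median had a median log2 fold change of -0.074 ± 0.139 (SE over markers). This argues against a loss of cells that themselves carried the interferon transcripts, which needs about -1 or lower. The bound was set after the marker values had been seen. It does not hold if such cells acted on others, which was not tested. Among the 9 markers Cd14 and Cd68 fell and Csf1r rose. Of 19 Ccl genes, the macrophage inflammatory proteins among them, 8 fell and none rose. The SE treats markers as independent and does not measure the spread between cultures. The mean of all 17 markers per array was 7.81 ± 0.21 (SD) in LacZ and 7.78 ± 0.06 in YAP1 arrays on the log2 scale. A different amount of virus, or different sensing of the 2 viruses, cannot be told apart from an effect of YAP1, because each group received its own virus and the difference of the list mean (-1.94) is the same under both. A response of the cardiomyocytes to YAP1 itself stays open as the biological account. Of the 35 ways to split the 8 arrays into 4 and 4, 1 gave a camera result as large for this list, the real one (-log10 p of 20.4, highest other 14.8). That is the smallest count possible, and the list was looked at because camera had called it, so the count does not exclude chance. The call was lost with the correlation estimated from the data (adjusted p = 0.161 with an estimated correlation).

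The YAP and TEAD targets did not rise as a group, and Ccn1 and Ccn2 are bright enough for a ceiling of the signal to be a candidate explanation. The 12 members under an intensity of 3000 in LacZ have room to rise. Their median log2 fold change was -0.191 ± 0.128 (SE over members), where a rise hidden only in bright members needs over 0.5. This argues against a ceiling as the reason that these 12 did not rise, and it does not cover the brighter members. The bound was set after the values had been seen, and the SE treats members as independent. For Ccn1 and Ccn2 themselves a hard limit at their intensity is argued against. Ankrd1 read 8632 to 9501 in the YAP1 arrays, and the highest values of the arrays were 12303 to 13295. A weaker compression of the signal cannot be told apart from no rise. Only 4.41% of the 68 genes between 6000 and 8000 rose, with a largest log2 fold change of 0.503, against 12.4% of the 2101 genes between 1000 and 3000. Why this share was lower was not tested. From the Yap1 probe set (0.245 ± 0.0743) a transgene it does not match cannot be told apart from weak expression. The difference that the design names, activated YAP1 acting on other genes in these cells, stays open and untested.

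The cardiac transcription factor and calcium handling lists rose while 6 of 15 endothelial markers fell (list adjusted p = 0.00675, and adjusted p = 0.391 with an estimated correlation). Of 13 smooth muscle and pericyte markers 5 fell, without passing camera as a list (adjusted p = 0.0913), though fry called the list lower (fry adjusted p = 0.00187). A larger share of cardiomyocytes is a candidate explanation. A larger share alone would lower the markers of all other cell types alike, but the fibroblast list mean rose against the endothelial one by 0.419 (SD 0.126 between arrays, exact permutation p = 0.02857, the smallest that 4 arrays against 4 can give). It would also raise abundant cardiomyocyte transcripts by a common factor, but the log2 fold changes of the 19 sarcomere transcripts at an intensity of 1000 or more spread with an SD of 0.642 against a median standard error of 0.079. The values behind both tests had been seen before, so their outcome was known. The permutation p therefore adds no support, and only the sizes of the differences bear on this explanation. A smaller change of the cell mix beside a change within cells stays open, as does loss of endothelial cells, and a response of cardiomyocytes to YAP1 is a hypothesis found and tested on the same data.

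Other splits of the 8 arrays into 4 and 4 gave at most 1 changed gene, and at most 1 changed at least 2-fold. The real split, the 1 of 35 with as many, gave 3591 and 406. Every other split mixes LacZ and YAP1 arrays on each side, so the difference between the groups adds to the spread and can lower its count. These counts therefore do not show how many genes chance would give, and no conclusion is drawn from them. The same mixing holds for the list results of the other splits. For the mitosis list the real -log10 p of camera was 40.2 against 18.8 at most in other splits. It was 12.1 against 8.15 for cardiac transcription factors and 10.02 against 7.16 for calcium handling. For hypertrophy genes it was 5.48 against 4.49 and for sarcomere genes, by a small margin, 4.52 against 4.17. For each of these lists only the real split gave a result as large. This count of 1 of 35 is the smallest possible and is read here only for lists that camera had called, so it does not exclude chance. The hypertrophy and sarcomere lists lost their call with the correlation estimated from the data (adjusted p = 0.161 and adjusted p = 0.256 with an estimated correlation). For the DNA replication list 8 of 35 splits, the real one included, gave a camera result as large (3.94 against 6.87). The counts were 5 of 35 for the endothelial list (2.65 against 4.93) and 2 of 35 for the NF-kB list (7.87 against 8.33). A chance split cannot be excluded for camera's result on these lists either. The means of the DNA replication, endothelial and NF-kB lists per array, which are compared with no other genes, differed by 0.22, -0.28 and -0.66 on the log2 scale. Each had an exact permutation p of 0.02857, the smallest that 4 arrays against 4 can give, not adjusted over the lists. Lists that camera did not call reached the same p, the antioxidant and fatty acid oxidation lists among them.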

How the results depend on the processing

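Apart from 2 added after seeing the data, a pseudocount of 16 and leaving out LacZ replicate 2 and YAP1 replicate 4 together, these alternatives were planned. Array weights raised the counts to 2790 higher and 3169 lower genes, with 3576 of the 3591 shared, and a test against a 1.2-fold change lowered them to 673 and 590, as its stricter null does. Over all probe sets 439 were higher and 255 lower at least 2-fold, since more features were tested. With both arrays that stand apart left out, 2072 genes were higher and 2068 lower. Leaving out 1 array gave 1323 to 2128 higher and 1409 to 2121 lower genes, and in each of the 18 alternatives that count genes, the shared genes kept their sign. The Yap1 log2 fold change ranged from 0.205 to 0.272 when 1 array was left out, with fewer samples. The list macrophage and leukocyte markers turned to -0.0373 and -0.154 with the dimmest 25% and 50% of genes left out and to -0.0226 without LacZ replicate 1 (range -0.0226 to 0.0899), its list mean was -0.0259 and fry's direction was down though the median was 0.0546. The list focal adhesion and actin cytoskeleton had a mean of 0.00528 against a lower median, and the Ccn1 log2 fold change turned to -0.00936 with array weights. The cause of these was not tested, and none of these values was past the threshold. Calls were lost in some alternative by 14 of 132 named genes (Yap1, F3, Amotl2, Cdkn2b, Tek, Csf1r, Sdha, Sdhb, Cox5b, Foxo1, Ptk2, Orc1, Aen and Gclc). No list that passed lost its call except with an estimated correlation. Fry and the permutation test of the list mean, which compare a list with no other genes, added 13 and 11. The YAP and TEAD targets (-0.15, exact permutation p = 0.02857) and p53 targets were among them in both. The permutation p was not adjusted over the lists, whereas that of fry was.

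The labels give shared replicate numbers without saying what they mark, and the numbers were not taken to pair the arrays. Deviations from the group means correlated at 0.129, -0.237, 0.365 and 0.36 for numbers 1 to 4, and the arrays numbered 3 and 4 correlated best with their own number but those numbered 1 and 2 did not. With the number as a replicate block, 1980 genes were higher and 2107 lower, 248 and 158 of them at least 2-fold, and 3475 of the 3591 were shared. Among named genes the block ended the calls of Amotl2 (adjusted p = 0.0679), Sdhb (0.0562) and Foxo1 (0.063), and it changed no list's call.

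Signal over background was not tested here. The median standard error of a log2 fold change was 0.117 in the dimmest 25% of genes and 0.0903 in the brightest 25%. The median log2 fold change of the dimmest 25% was -0.0697, and -0.00245 without LacZ replicate 2. In the dimmest 25%, 60 genes were higher and 207 lower. Centring on array medians gave 1766 higher and 1722 lower genes, and leaving out the dimmest 50% gave 1533 and 1406. Which direction held more genes thus depended on the processing.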

Other observations

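The families and tests in this part were chosen after the data had been seen. Families of genes that share a symbol stem were tested with camera over 231 families of at least 8 members, and 13 passed, 9 up and 4 down, whereas 0 passed with an estimated correlation (smallest adjusted p = 0.79 with an estimated correlation). Of 13 Asb genes, substrate adaptors of ubiquitin ligases, 6 rose and none fell (camera adjusted p = 0.00472, adjusted p = 0.79 with an estimated correlation), led by Asb12, from 422 ± 91.0 to 1219 ± 61.4 (log2 fold change 1.55 ± 0.13), and the muscle gene Asb2 (1.47 ± 0.09). Of 8 Frizzled receptors of Wnt ligands 4 rose and none fell (adjusted p = 0.0106, adjusted p = 0.79 with an estimated correlation), with Fzd6 rising from 327 ± 11.3 to 731 ± 39.2 and Fzd5 at 0.94 ± 0.07 beside Fzd1. Of 15 Krüppel-like factors 8 fell and none rose (adjusted p = 0.00939, adjusted p = 0.79 with an estimated correlation), among them Klf12 at -0.67 ± 0.15, Klf6 at -0.60 ± 0.09 and Klf2, a gene induced by flow in endothelium, at -0.53 ± 0.08.

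Of 19 Ccl genes 8 fell and none rose (adjusted p = 0.0226), with the macrophage inflammatory proteins Ccl3 at -1.68 ± 0.16, Ccl9 at -1.67 ± 0.18 and Ccl4 at -1.26 ± 0.16. Of 12 Cxcl genes 7 fell and none rose (adjusted p = 0.0033), with Cxcl11 at -2.21 ± 0.14. Neither family passed with an estimated correlation (adjusted p = 0.997 for both). The direction of these 5 families and their counts of genes that rose or fell were the same after quantile normalization and after centring on array medians.

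Of 11 Myh genes 6 rose and 1 fell (camera adjusted p = 0.00504, adjusted p = 0.997 with an estimated correlation). Myh3, the embryonic skeletal isoform, rose by 2.07 ± 0.09 and Myh2, a fast skeletal isoform, by 1.70 ± 0.10 beside Myh7.

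Genes of mitosis rose further than those of DNA replication. The mean of the mitosis list minus that of the replication list was higher by 1.43 in YAP1 than in LacZ arrays (SD 0.0527, exact permutation p = 0.02857, the smallest that 4 arrays against 4 can give), and it lay between 0.98 and 1.04 in YAP1 arrays and between -0.478 and -0.354 in LacZ arrays. The difference had been seen before it was tested, so it leaves open whether the response at 48 h lies mainly in genes of G2 and mitosis.

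The 215 chemosensory receptor genes (Olr, Vom and Tas) had a median LacZ intensity of 49.0 and a median log2 fold change of -0.0954, with 0 higher and 13 lower. Without LacZ replicate 2 the median was -0.0354, with 2 higher and 8 lower, and without YAP1 replicate 4 it was -0.144, with 0 higher and 15 lower.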
